A study of Mus musculus with 4 samples.

How the data were processed

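Gene expression was measured in pancreatic islets of C57BL/6 mice aged 5 to 6 months, per the labels, which name WT littermates and GPR41 transgenic (Tg) mice with 2 arrays each. Islets were kept in RPMI medium before total RNA was purified with Tri-Reagent and Direct-zol columns, and 250 ng of total RNA was labelled for Affymetrix Mouse Gene 2.0 ST arrays, per the labels' protocols. The deposited values are on a log2 scale, as read from their range of 2.87 to 13.9, and the submitters' processing notes name Partek and RMA (robust multi-array average, which corrects background, normalises arrays to each other by quantiles and summarises probes) without versions. A genome build is not given in the sources used here, so no coordinates are printed. Each group was taken from the sample titles, and all 4 columns of values were used. The titles call the 2 arrays of a group biological replicates, without saying whether each holds islets of 1 mouse or of several.

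The table held 27037 probesets, each the set of probes that reads a transcript. The platform annotation paired 23521 of them with 1 gene symbol and 1814 with several, and it left 1702 unnamed. Probesets with several symbols or none were left out of the main comparison. Where a gene had several probesets, the one with the highest mean over the 4 arrays stood for it, which left 1341 dimmer probesets unused and gave 22180 genes, with no filter on dim genes. Genes whose probesets disagreed are named where they are reported.

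Differences are Tg minus WT on the log2 scale, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all 22180 genes. The 4 arrays left 2 residual degrees of freedom, and the moderation added 3.76. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so all p-values of single genes between the groups rest on limma's model. A second, descriptive count took genes that differed at least 1.5-fold with an unadjusted p under 0.05, without correction for the number of genes. The number of arrays limits the precision.

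Before the data were examined, 28 gene lists were fixed: 18 of pathways and islet functions, 9 of cell types other than the beta cell, and 1 of sex-linked genes kept as a check. Of their 786 symbols, 712 had a single-gene probeset, and older symbols were matched through a GRCm38 gene table used only for names and gene order. The 26 lists with at least 5 measured members, sex-linked genes aside, were tested with camera and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 26 lists. Camera with a correlation estimated from each list and fry, a rotation test of whether the genes of a list move on balance in 1 direction, stand beside it. Counts within a list are given over all genes and adjusted over the list alone.

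The genes named in the text followed a rule fixed at the same time. In each direction it took the 12 genes with the largest difference among those with an adjusted p under 0.05, groups that did not overlap and a mean in the higher group above the median of all tested genes, leaving out symbols of predicted or unnamed genes. It added up to 4 members with the smallest p from each list, and always, among others, Ffar3, Ffar2, Ffar1, Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa and Slc2a2. Ins1 had no single-gene probeset in the annotation used and was not analysed here. A gene named outside the rule is said to be so.

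The steps were tested on simulated data of 22180 genes on 2 arrays against 2, with 200 genes changed, in 20 simulations. The fit recovered 62.9% of 2-fold and 97.3% of 4-fold changes, with 5.01% false calls and 0 calls of the wrong sign. A list shifted by 0.3 was called in 20 of the 20 simulations with the preset correlation and in 0 with an estimated correlation, and 0 of 500 unshifted lists were called. The simulated genes varied independently of each other, with normal errors and variances drawn from the prior that limma had fitted to these data. The rates therefore hold only where that model does, and they do not test the calls in the real data.

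The alternatives were the mean of a gene's probesets, every probeset by itself, all probesets of the table, a filter at the median level, quantile normalisation once more, centring of arrays, a variance trend with and without a robust prior, an ordinary linear model without moderation, the replicate number as a block, a 2-fold limit, the other list tests, and each array left out in turn. Leaving Ffar3 out of the gene lists was added after the data were seen.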

Results

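Gene expression was compared between pancreatic islets, the hormone-secreting cell clusters of the pancreas, from WT littermates and from GPR41 transgenic (Tg) mice, with 2 arrays in each group. GPR41 is a G protein-coupled receptor for short-chain fatty acids, and its mouse gene is Ffar3. The comparison asked which islet genes accompany the GPR41 transgene, in a study of insulin secretion and metabolism. Median log2 values of the 4 arrays lay between 6.43 and 6.47. Pearson's r over all 27037 probesets, which are not independent replicates, was 0.991 between the WT arrays and 0.994 between the Tg arrays. Across the groups it was 0.986 to 0.987. In the tested genes, a first principal component with 55.8% of the variance separated Tg from WT. A second with 27.9% separated the WT arrays from each other.

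Ffar3 rose 18.7-fold in Tg islets, from log2 values of 7.09 and 6.47 on the WT arrays to 11.02 and 10.98 on the Tg arrays (difference 4.22, SE 0.21, adjusted p = 0.0020). The neighbouring receptor genes Ffar2 (difference 0.13, SE 0.11) and Ffar1 (difference -0.22, SE 0.16) did not pass the test. The labels do not give the sequence or promoter of the transgene, so the probeset cannot separate its transcripts from those of the mouse gene. Without variance moderation, Ffar3 had an adjusted p of 0.472, and over 13 alternatives its adjusted p ranged from 0.00021 to that value.

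In all, 199 of 22180 genes changed at an adjusted p under 0.05, 149 higher and 50 lower in Tg, and 159 of them by at least 2-fold. Cldn8, which encodes a tight junction protein, rose 32.2-fold (difference 5.01, SE 0.22). Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, rose 16.0-fold (95% confidence interval of the log2 difference 3.43 to 4.58). An immunoglobulin kappa variable segment had a difference of 6.52 (SE 0.56), and its Tg arrays stood apart at 9.69 and 11.45. Lrrc55, an auxiliary subunit of a potassium channel (4.49), Fbxw24 (4.13) and Gbp11, of the interferon-inducible guanylate-binding proteins (4.09), rose by more than 4 log2 units. The segment and Fbxw24 lay below the first quartile of both WT arrays, and Tph1 and Lrrc55 below that of 1, so the sizes and order of these differences are uncertain. Matn2, a matrix protein (3.50), the synaptotagmin gene Syt10 (3.49), Tmem47 (3.47), the flavin monooxygenase gene Fmo1 (3.43) and Plppr5 (3.33) followed. Dimmer second probesets of Lrrc55 (0.34) and Tmem47 (0.51) did not pass the test.

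Decreases were smaller, and only 3 of the 50 reached 4-fold. The largest was that of Gm4791 (-2.79), a predicted gene that the naming rule left out by its symbol. Dapl1 fell 5.51-fold (difference -2.46, SE 0.20), and Tat, the tyrosine aminotransferase gene, fell 4.15-fold (difference -2.05, SE 0.13). Vsnl1, a neuronal calcium sensor (-1.94), Pdyn, the precursor of dynorphin opioid peptides (-1.79), and Jam2, a junctional adhesion molecule (-1.69), also fell. The trace amine receptor gene Taar1 (-1.57) and the G protein regulator Rgs16 (-1.50) fell as well, as did Smoc1 (-1.60), Necab2 (-1.47), Zim1 (-1.45), Spock1 (-1.44) and Pappa2 (-1.44).

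**Figure D1:**
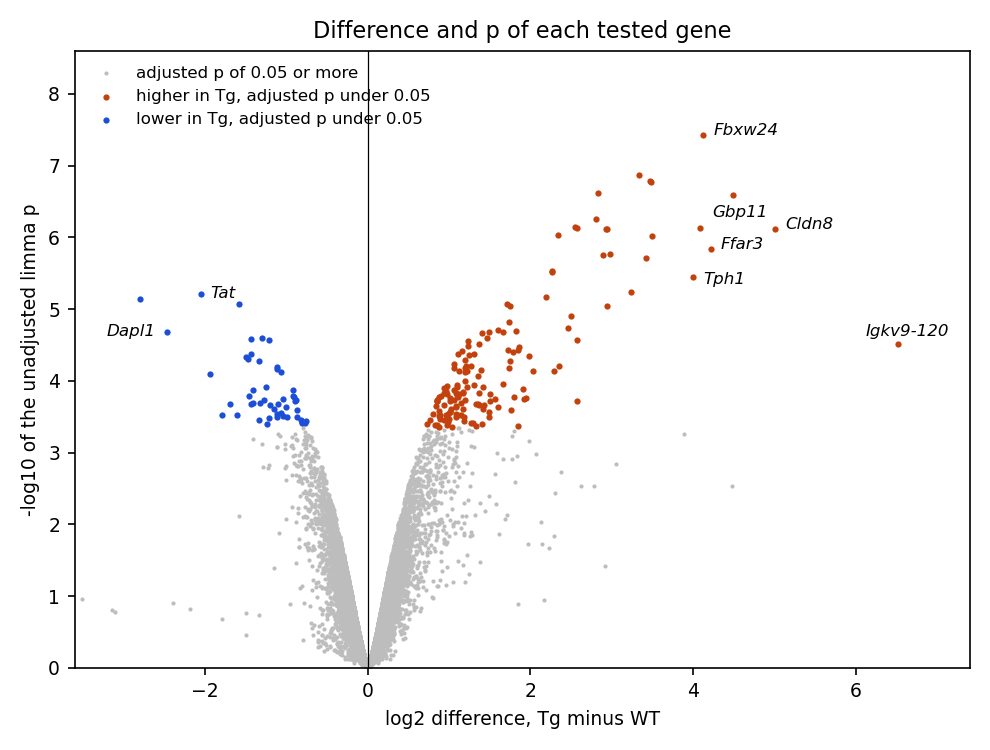
Log2 difference (Tg minus WT, x axis) of each of 22180 tested genes against -log10 of its unadjusted limma p (y axis), with the 149 genes higher and 50 genes lower in Tg at an adjusted p under 0.05 in colour. Ffar3 lies at 4.22 and Dapl1 at -2.46.

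**Figure D2:**
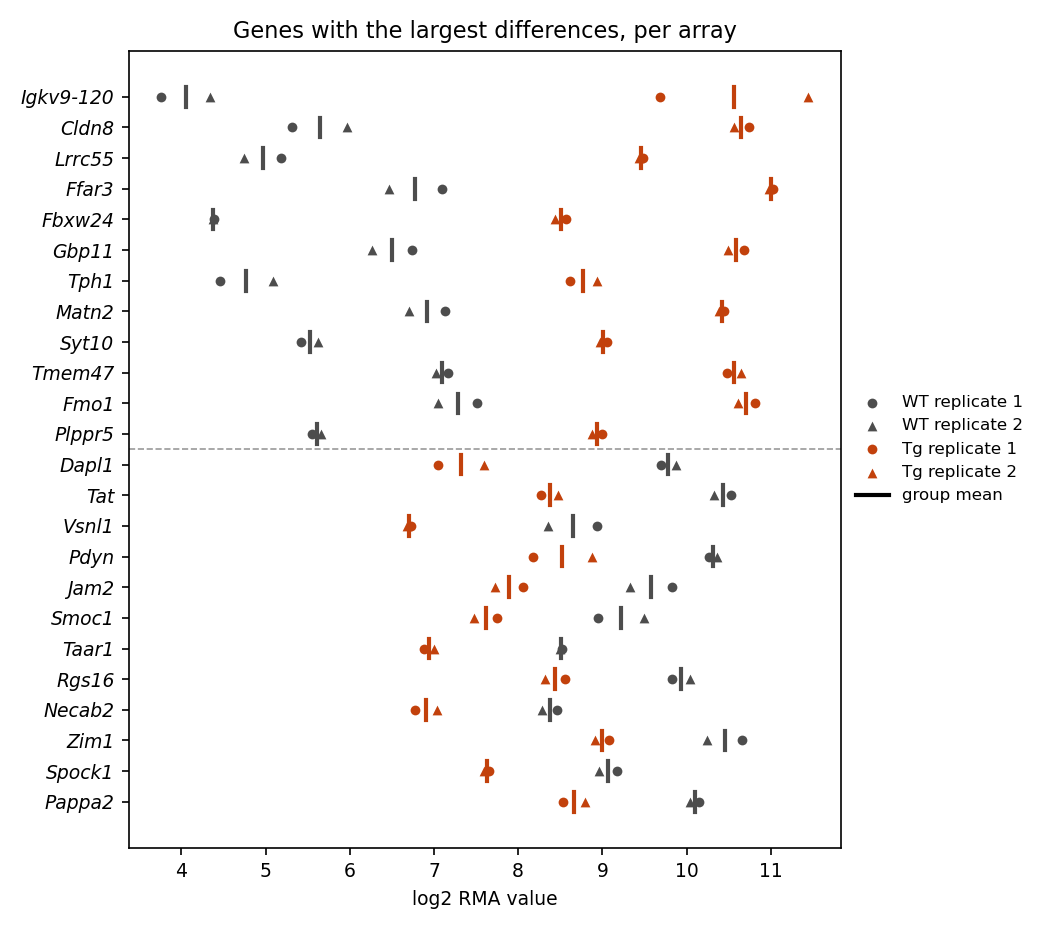
Log2 RMA values (x axis) on each of the 4 arrays for the 12 genes per direction taken by the naming rule, with circles and triangles for replicates 1 and 2 and a bar for each group's mean. Every gene shown has both Tg values on 1 side of both WT values.

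Across the tested genes, 42.3% had groups that did not overlap, against 33.3% by chance. A further count without correction found 772 genes at least 1.5-fold different at an unadjusted p under 0.05, 521 higher and 251 lower in Tg. Its lower genes numbered 483 without WT replicate 1 and 410 without WT replicate 2. With each array left out in turn, which leaves 1 array in a group, the adjusted count fell. Few lower genes passed the adjusted threshold without a Tg array, which does not show that their differences shrank. The adjusted count was 0 without moderation, where 1928 genes had an unadjusted p under 0.05 against 2627 with limma. Only 1107 genes were in both counts. For either count, not for the overlap, 1109 genes would be expected under that threshold if no gene differed. A variance trend with a robust prior gave 347.

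Genes of the list that responds in islets to pregnancy, prolactin and growth hormone were the group with the most individual calls. Of 18 measured members, 9 rose over all genes and none fell, with a median difference of 0.84, and 13 were higher and 1 lower adjusted over the list alone (camera adjusted p = 3.4e-15). Its adjusted p was 0.310 with an estimated correlation (0.175 for this list) and 0.040 by fry. Where the estimated correlation lies above the preset one, as here, camera's p with the preset correlation may be far too small. When the arrays were regrouped so that each side held 1 WT and 1 Tg array, camera with the preset correlation called 6 and 9 lists. Between Tg and WT it called 11, so such a call alone is weak evidence of a group difference. In the simulations, camera with an estimated correlation called 0 of 20 lists shifted by 0.3. Missing the threshold in that test therefore says little against a shift, here and for the lists below. Tph1, Matn2, Gbp8 (3.23, SE 0.20) and Tnfrsf11b, which encodes the decoy receptor osteoprotegerin (2.93, SE 0.13), rose most, and the other 5 were outside the naming rule and chosen after their values were seen. These were Tph2 (1.73), the cytokine signalling inhibitors Cish (1.08) and Socs2 (1.10), Neb (2.50) and Ivd (0.96), of which Cish had a second probeset at 0.41 and Socs2 one at 0.77 that did not pass.

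Markers of immune cells were higher in Tg islets as a group. All 30 measured members were higher, with a median difference of 0.94, and 25 passed adjusted over the list alone, although over all genes only Coro1a, an actin-binding protein of leukocytes, did (0.94, SE 0.10; camera adjusted p = 5.6e-23). The list's mean was 7.17 and 7.0 on the WT arrays and 8.21 and 7.90 on the Tg arrays. Its adjusted p was 0.310 with an estimated correlation and 0.120 by fry. The estimated correlation, 0.119, lay above the preset one, so the camera p of 5.6e-23 may be far too small. Cd68, a macrophage marker (0.75, SE 0.11), Tyrobp (1.10, SE 0.17) and Fcgr1 (0.73, SE 0.12) did not pass over all genes.

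Lists of interferon response and antigen presentation (median 0.27), inflammation and NF-kB response (0.14) and cell cycle (0.14) were called up by camera beside these immune markers. With an estimated correlation the adjusted p was 0.314 for interferon response, 0.525 for inflammation and 0.710 for cell cycle. By fry it was 0.127, 0.499 and 0.513. In the interferon list, 2 of 34 members rose over all genes and 12 adjusted over the list alone. The 2 were the chemokine genes Cxcl10 (1.02, SE 0.13) and Cxcl9 (0.94, SE 0.12), while Ifit3 (0.49) and Ifit1 (0.66) did not pass. In the inflammation list, Il1b rose (0.94, SE 0.11), with 5 members higher and 1 lower adjusted over the list alone. The lower one was the interleukin receptor gene Il1r1 (-0.71), and Il1a (0.87) and Tnf (0.56) were among the higher ones. The cell cycle list had 0 of 44 members past the test over all genes, with Ttk at 0.55 and Kif11 at 0.72, and 0 adjusted over the list alone. The inflammation median was 0.028 without WT replicate 1 (adjusted p = 0.259) and 0.48 without WT replicate 2, and the interferon median was 0.18 without WT replicate 2. The cell cycle list's mean was 6.97 and 7.02 on the WT arrays and 7.36 and 7.05 on the Tg arrays, and its median was 0.011 without Tg replicate 1 (adjusted p = 0.256).

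Endothelial markers were higher in Tg for 22 of 22 members (median 0.35) and mesenchymal markers for 20 of 26 (median 0.15), with no member past the test over all genes. The leading members were Cd34 (0.83, SE 0.20) and Cdh5 (0.62, SE 0.16), and the collagen-binding proteoglycan Dcn (1.79, SE 0.26) and Fn1 (0.92, SE 0.17). Camera called both lists. With an estimated correlation the adjusted p was 0.525 for endothelial (correlation 0.58) and 0.314 for mesenchymal markers (correlation 0.026). By fry it was 0.371 and 0.257. The mesenchymal median ranged from 0.054 to 0.19 with each array left out. Camera also called the list of metabolite-sensing receptors (median 0.14), whose adjusted p was 0.525 with an estimated correlation and 0.149 by fry. In this list 11 of 15 members were higher and only Ffar3 passed over all genes, with Cd36 at 0.65, Hcar2 at 0.36 and Hcar1 at -0.47. Without Ffar3, left out after the data were seen, camera did not call it (median 0.13, adjusted p = 0.090), and with it the median was 0.22 without WT replicate 1.

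The 3 lists that camera called down were the circadian clock (median -0.19), fatty acid and cholesterol synthesis (-0.19) and the markers of alpha, delta, PP and epsilon cells (-0.26). With an estimated correlation the adjusted p was 0.310 for the clock, 0.310 for synthesis and 0.729 for the endocrine markers. The correlations estimated for the clock (-0.048) and synthesis lists (-0.027) lay below the preset 0.01, so correlated genes do not explain their higher p. Fry called the clock (adjusted p = 0.0085) and synthesis lists (0.010) but not the endocrine markers (0.447). Of 18 clock genes, 16 were lower and 8 passed adjusted over the list alone but 0 over all genes, among them Npas2 (-0.54, SE 0.10), Per3 (-0.43, SE 0.11) and Cry2 (-0.42, SE 0.11). In the synthesis list, Fads2, a fatty acid desaturase gene, fell (-1.30, SE 0.11), and 24 of 30 members were lower, with Srebf1 at -0.46 and Fasn at -0.34. The non-beta endocrine list had 15 of 19 members lower and 0 past the test over all genes, with Etv1 at -0.94 and Irx2 at -0.86. Its median was -0.14 without WT replicate 1 (adjusted p = 0.145) and -0.42 without WT replicate 2. The clock median was -0.29 without Tg replicate 2. In the other 2 splits of the 4 arrays into 2 and 2, which mix the groups, camera called 6 and 9 lists, against 11 between Tg and WT.

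Hormone and beta cell genes did not pass the test. The differences were 0.04 for Ins2 (SE 0.11), -0.15 for Gcg (SE 0.10), -0.32 for Sst (SE 0.14), 0.06 for Ppy (SE 0.11), -0.11 for Pdx1 (SE 0.13), -0.14 for Mafa (SE 0.12) and -0.05 for Slc2a2 (SE 0.13). Ppy, at 13.69 on WT replicate 1, was the highest value of that array, and Gcg (WT mean 13.63) and Sst (13.32) lay near the top. Differences at such levels may be compressed, so a change of these hormone genes is not excluded. None of 30 beta cell identity genes passed (list median -0.06), with Ucn3 at -0.60 and Chgb at 0.58. The insulin secretion list (median -0.09) held 1 call, the calcium channel gene Cacna1c, which fell (-0.87, SE 0.11). The list of G protein and cAMP signalling (median -0.03) held Rgs16, and that of CREB targets (median 0.17) held Ppargc1a, a transcriptional coactivator of mitochondrial genes (-1.41, SE 0.17). The duct list (median -0.02) held the chloride channel gene Cftr, which rose (2.30, SE 0.23), and Prom1, which fell (-1.0, SE 0.12). In the TCA cycle list (median -0.09), Gpd2 was at -0.69 without passing.

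The remaining lists had medians of 0.07 for hypoxia and oxidative stress, 0.05 for adipocyte markers, 0.02 for fatty acid oxidation, 0.0014 for disallowed genes of the beta cell, -0.0042 for the respiratory chain, -0.012 for Schwann cells, -0.02 for acinar cells, for glycolysis and for the unfolded protein response. None of these passed camera or had a member past the test over all genes. Camera's direction was up against a median below 0 for the respiratory chain, Schwann, acinar and unfolded protein response lists, and the mean of the disallowed genes was -0.03. Acinar markers, of the enzyme-secreting exocrine cells, differed between arrays of 1 group, with list means of 9.69 and 10.84 on the WT arrays and 10.41 and 10.02 on the Tg arrays. Only 2 red blood cell markers were measured (median 0.05), and sex-linked genes had a median of 0.06 with 0 of 6 past the test.

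**Figure D3:**
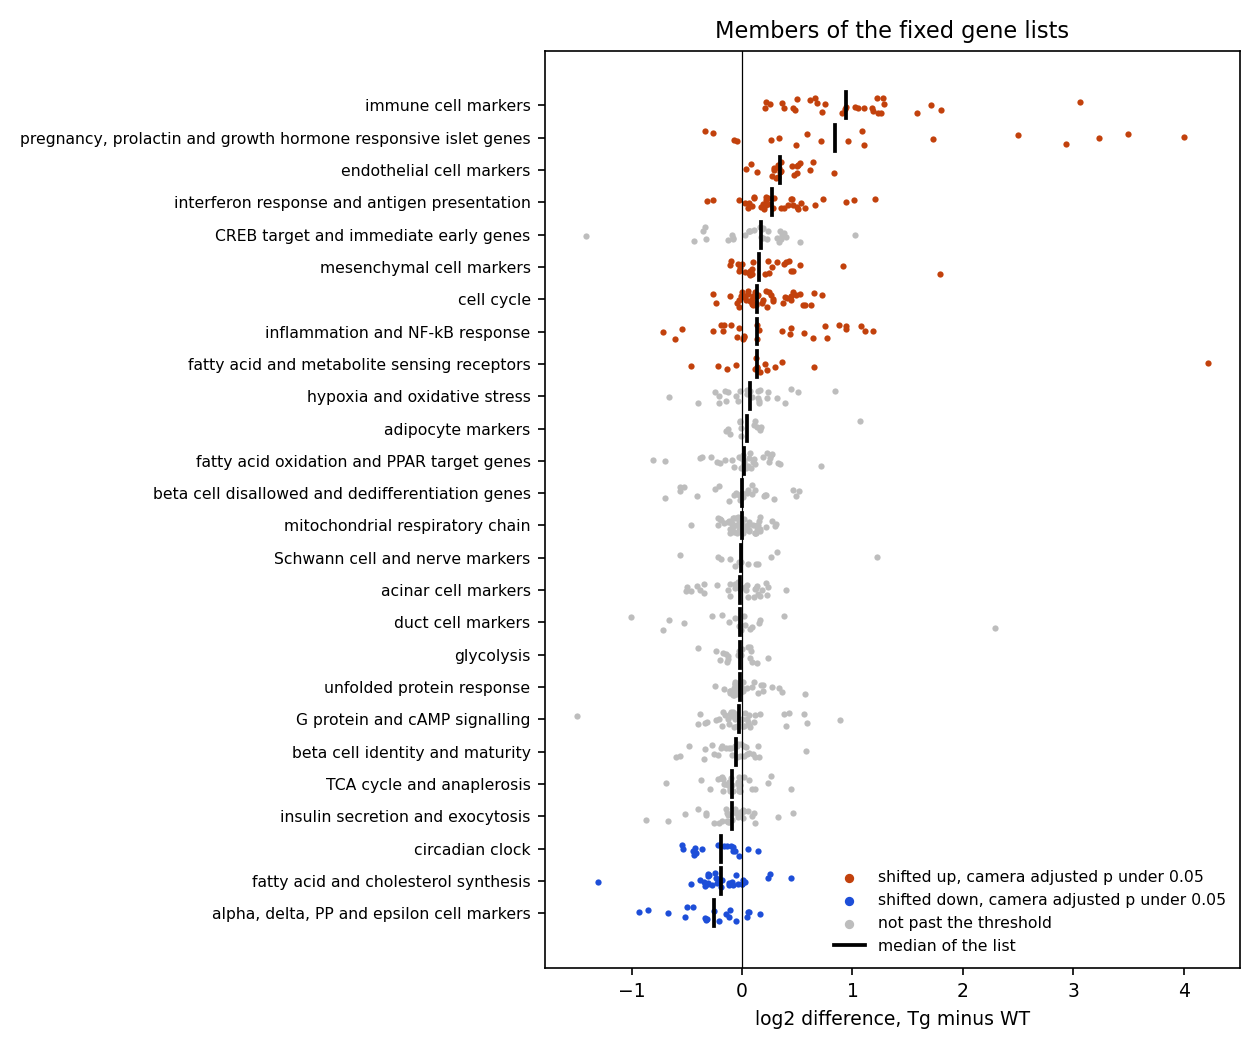
Log2 difference (Tg minus WT, x axis) of each measured member of the 26 tested gene lists, with a black bar at the list's median and colour for lists called by camera with the preset correlation. Immune markers (median 0.94) lie at the top and non-beta endocrine markers (-0.26) at the bottom.

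**Figure D4:**
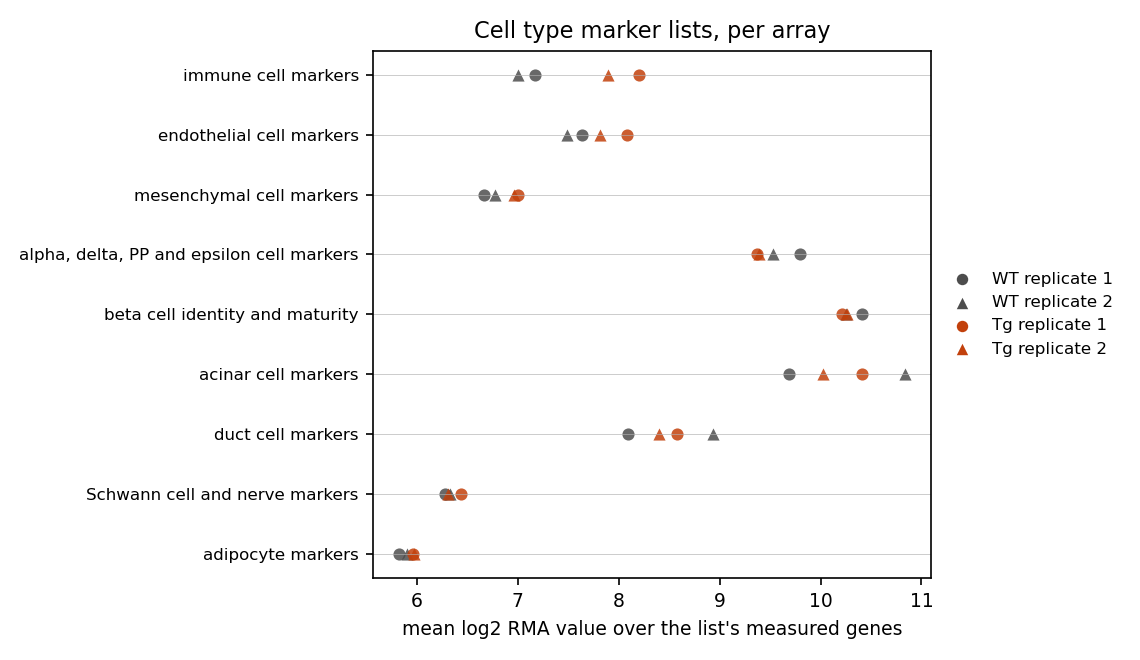
Mean log2 RMA value (x axis) over the measured genes of 9 lists, on each of the 4 arrays, with circles and triangles for replicates 1 and 2. Immune markers stand at 8.21 and 7.90 on the Tg arrays against 7.17 and 7.0 on the WT arrays, and acinar markers differ more between the WT arrays (9.69 and 10.84).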

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

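Probesets outside the 1-gene comparison also differed between the groups. In a fit of all 27037 probesets, 13 of the 1814 that name several genes were higher in Tg at an adjusted p under 0.05 and 0 were lower. Of the 1702 that name no gene, 14 were higher and 1 was lower. They were brought up because they lie in data the comparison of genes does not use. The largest difference was 3.79 among the unnamed probesets, from a WT mean of 5.97 to a Tg mean of 9.76, and 3.23 among those of several genes.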

How the results depend on the processing

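All alternatives but 1 were planned. Against 199 genes past the adjusted threshold, the mean of probesets, single probesets, the level filter, quantile normalisation, centring, all probesets and the variance trend gave counts between 195 and 274, with 191 to 197 of the 199 shared except for the level filter, which shared 151 of its 235. The count was 347 with a variance trend and robust prior, 0 without moderation (1928 at an unadjusted p under 0.05, against 2627 with limma) and 38 to 135 with each array left out, where the lone array of a group is assumed to vary like the others. With the replicate block it was 24 (23 higher and 1 lower), of which 23 were shared. Replicate differences correlated at -0.063 between the groups over all genes. This does not settle whether arrays with the same number share a litter or day, which the labels do not say. The 772 genes of the 1.5-fold count became 416 without moderation and 262 at a 2-fold limit, and 846 to 1078 with each array left out. Ffar3 kept its difference of 4.22 without moderation, at an adjusted p of 0.472, and stayed past the threshold in the other 12 of 13 alternatives (3.91 to 4.53). Against 11 lists, camera called 0 with an estimated correlation (4 at an unadjusted p under 0.05), fry called 3, and camera called 10 to 18 with each array left out, of which 9 to 11 were among the 11. With Ffar3 left out of the lists, an alternative chosen after seeing the data, it called 10. Named genes past the threshold kept their call in 289 of 404 alternatives and lost it in 115, and 0 reversed. Those not past it gained a call in 28 of 1213 alternatives. Of the named genes not past the test, 10 turned sign at least once, and of those given in the text Pdx1 lay between -0.25 and 0.040 with each array left out, Slc2a2 between -0.17 and 0.067 (0.0015 without Tg replicate 1), Ins2 between -0.016 and 0.096 and Ppy between -0.0071 and 0.13. The cause was not tested. Genes near the background signal give compressed differences, but Pdx1 (WT mean 9.41), Slc2a2 (11.05), Ins2 (12.52) and Ppy (13.66) do not lie near it.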

Other observations

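The tests of pregnancy, of the endocrine share, of carried-over leukocytes, of flanking DNA, of other splits, of gene families and of neighbours were chosen after the values they bear on were seen; those of Stat5 targets and of the mouse hormone genes were chosen before. The rule for naming genes did not name Gbp4, Gbp10, Fmo2, Fmo4, Cxcl11 or the Reg3 genes, which were picked after their values were seen. Among 597 families of at least 5 measured genes that share a symbol stem, 4 held more changed genes than chance by Fisher's exact test with Benjamini-Hochberg adjustment. The test takes genes as independent, which related genes that lie together need not be, so its p-values may be too small. Of 10 guanylate-binding protein genes, 4 rose (Gbp4, Gbp8, Gbp10 and Gbp11; adjusted p = 0.00076). Of 6 flavin monooxygenase genes, 3 rose (Fmo1 3.43, Fmo2 1.31 and Fmo4 1.08; adjusted p = 0.0042). The other families were 3 of 13 Cxcl chemokine genes (Cxcl9, Cxcl10 and Cxcl11) and 3 of 13 immunoglobulin kappa variable segments, each at an adjusted p of 0.028, and similar probes of these segments can share transcripts. Of the 197 changed genes with a known place, 52 had another within 5 tested genes, a share of 0.264. The mean in 1000 random draws was 0.087 (permutation p = 0.001, the smallest these draws can give). Some of these neighbours were of 1 family, such as Gbp4 and Gbp8. Others were not, such as Aqp4 and Chst9 or Il1b and Pdyn, so families do not account for all of them.

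The regenerating genes Reg3a, Reg3b and Reg3g differed more within the WT group than between groups. Reg3b was 9.91 and 12.59 on the WT arrays and 10.14 and 11.14 on the Tg arrays, and Reg3g was 8.62 and 11.57 against 9.17 and 10.67.

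Genes that respond to prolactin and growth hormone in islets had a median difference of 0.84, with 14 of 18 higher, 4 lower and an adjusted p of 0.310 with an estimated correlation. Pregnancy or lactation of the Tg mice is argued against by 3 of 5 Y-linked genes above the median of their array on both Tg arrays, with Xist below the first quartile on all 4 arrays. Signalling through the prolactin or growth hormone receptor, for example from hormone sequence within a transgene construct, may contribute. These receptors activate Stat5, and 9 of its targets known from other tissues had a median of -0.031 (bootstrap interval -0.18 to 0.22), with members of both signs. The 9 hold no gene of the list, and so leave out Cish (1.08, second probeset 0.41) and Socs2 (1.10, second probeset 0.77). Both passed over all genes, so the 9 targets cannot decide this. The highest upper 95% bound of the differences of mouse Gh and Prl, 0.806, lies below the bound of 1 set beforehand as evidence against their transcription, but after this result was seen the explanation was kept open, since both genes lie at low levels (28.5th and 14.5th percentile). An effect of GPR41 itself was not tested apart from the transgene, and the explanations left open cannot be told apart here.

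Immune cell markers had a median difference of 0.94, with 30 of 30 higher and an adjusted p of 0.310 with an estimated correlation. A smaller share of endocrine cells would raise markers of all other types alike, if their probesets respond alike. The immune list rose by 0.582 more than the endothelial list (SE over arrays 0.026), which under that condition argues against a smaller share as the whole cause. This gap was already visible in the list means when the test was chosen, and its SE rests on 2 arrays per group. The mean difference was 1.61 for 7 lymphocyte markers and 0.63 for 12 macrophage markers, against 0.39 for the endothelial list. Acinar (median -0.02), duct (-0.02), Schwann cell (-0.012) and adipocyte markers (0.05) did not rise as these did. Of the 30 immune markers, 0 also stand in another list and 17 lay above the median level of genes in WT islets already. Leukocytes carried over with lymph nodes or blood at isolation may contribute, since 7 lymphocyte markers differed by a mean of 0.634 between the Tg arrays and 12 macrophage markers by -0.062, although Ighm was lower on the first Tg array (11.03 against 12.77) and the other 6 lymphocyte markers differed by 1.031. With 2 arrays per group this cannot be told apart from leukocytes within the Tg islets, which the design leaves untested.

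The share of changed genes with a changed neighbour, 0.264, was the first test tried for DNA of another strain and left it undecided, and the chromosome share was chosen after that result. DNA of another strain around the insertion site of the transgene could change genes of 1 chromosome, but the chromosome with the most changed genes, 6, held 9.64% of them (95% exact binomial interval 5.91 to 14.7) against 5.46% of the tested genes, and they lay on 20 chromosomes, which argues against this as the main cause. For the 199 changed genes between Tg and WT, of the 3 splits of the 4 arrays into 2 and 2, 1 gave as many genes, the real split with 199, and the highest other gave 0, but 3 splits are too few for a share under 0.05. Strain DNA scattered over the genome was not tested.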
